A study of Homo sapiens with 4 samples.

How the data were processed

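The series holds 4 RNA-seq libraries of the T24 cell line, 2 treated with control siRNA and 2 with siRNA against NSUN2. The sequence and number of the siRNAs against NSUN2 are not given in the sources used here. Per the labels' protocols, poly(A) RNA was enriched with oligo(dT) beads and made into libraries with a stranded mRNA kit, and these were sequenced as read pairs on an Illumina instrument. The authors deposited 1 table of raw counts per Ensembl gene with 1 column per library. Per the submitters' processing notes, HISAT2 and HTSeq were used with the genome build hg19. Their versions, the gene annotation and the strand setting of the counting are not given in the sources used here. Reads of genes that overlap, of antisense partners and of near-identical copies may therefore be lost or assigned to either gene.

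The table lists 62893 genes, of which 31524 had 0 counts in every library. Every row named a gene, and every column was used. Symbols were found for 51226 IDs in a table of gene names, and for 51537 when the GENCODE release 29 annotation was added. That annotation is on GRCh38 and the counts are on hg19, so no coordinates are given, and the reference was used only through gene IDs for symbols, transcript sequence, GC content and length. These were known for 96.4% of the genes tested.

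Groups and replicate numbers came from the sample titles. Library totals ran from 33633249 to 215936965 counts, so that 1 CPM stands for 33.6 to 216 counts. The libraries of a pair differed by far more than sampling noise (chi-square per degree of freedom 20.6 for siControl and 13.4 for siNSUN2), which does not tell whether they came from separate cultures. They were counted as the separate samples that the labels name. The groups of 2 are too small for a permutation test of single values or for regrouping the samples.

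The main test was the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3 (robust, TMM factors, filterByExpr by group, no block for the replicate number), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The filter kept 16889 genes with 99.96% of the counts. Log2 fold changes are siNSUN2 over siControl, and their standard errors were derived from the F statistic. CPM values use library sizes scaled by TMM factors, which lay between 0.985 and 1.02. The biological coefficient of variation was 0.14. Named genes followed a rule fixed before the data were examined: NSUN2, HDGF, YBX1, ALYREF and called m5C factors; the 7 largest called rises and the 7 largest called falls with average log2 CPM of at least 2, no overlap in CPM between the groups and no clone-type name; and for each gene list up to 3 members with the smallest p if the list passed, otherwise up to 2 members with the smallest p if they were called. CD44, ITGAM, HBB, HBA2, VWF, MMP2, SPARC and MMP14, and the genes named for families and for differences between replicates, were chosen after their values were seen. Some genes that the rule takes are not reported here.

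The 34 gene lists were also fixed beforehand. Lists with at least 5 measured members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, two-sided and adjusted over the 30 lists tested, and again with an estimated correlation and with fry. The test was checked on counts simulated for this comparison from the means of the siControl libraries and the sizes of all libraries. Far fewer genes were changed there than the 52.6% called in the data, so the shares that follow hold for the simulated setting. Among 16889 genes, 200 were changed 1.5-fold to 4-fold and 40 others were raised by 0.4 on the log2 scale for the list test. Of the 200 genes, 82% were recovered, with 74.6% of those changed 1.5-fold, 76.1% of those changed 2-fold and 95.5% of those changed 4-fold. Of the 213 calls, 28 (13.1%) were among the 15970 unchanged genes kept by the filter, more than the nominal 5%.

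For 7-base words, the longest annotated 3′ UTR of each coding gene (at least 50 bases, average log2 CPM above 1) was searched. Log2 fold changes were adjusted for UTR length and GC content, and 16166 words found in at least 50 genes were scored by a z score against all other genes. Coding sequences of genes without ACCCTA in the 3′ UTR were later searched in the same way, with and without genes of the ZNF family or encoding the zinc finger linker TGEKP. The search found 5 of 5 planted words in simulated data over 10528 genes. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.

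Alternatives chosen before the data were examined were DESeq2 1.42.0, limma-voom, non-robust edgeR, other scaling factors, other low-count filters, other gene list tests and prior counts, the replicate number as a block, each library left out in turn, the 50 most abundant genes left out, and stricter thresholds. Added later were libraries thinned to the shallowest total, word-bearing genes left out, and loess offsets on GC content and length (span 0.5) in each library. Microarray, protein and methylation data were not analysed here.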

Results

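Poly(A) RNA of T24 cells, a line derived from a human carcinoma of the urinary bladder, was sequenced after treatment with control siRNA (siControl) or siRNA against NSUN2 (siNSUN2). NSUN2 encodes a methyltransferase that places 5-methylcytosine (m5C) on tRNAs and other RNAs. The 4 libraries formed 2 groups of 2. Their total gene counts were 42298529 for siControl replicate 1, 215936965 for siControl replicate 2, 92640839 for siNSUN2 replicate 1 and 33633249 for siNSUN2 replicate 2, so that the deepest held 6.42 times the counts of the shallowest. Nothing in the labels says whether the replicates were separate cultures, so the p-values given here measure only the spread between these libraries, which may be technical. The comparison asks which transcripts differ in abundance when NSUN2 is knocked down.

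The targeted transcript was measured first. NSUN2 (ENSG00000037474) stood at 283 ± 2.53 CPM (library-size-scaled counts, mean ± SD, n = 2) in siControl cells and at 29.9 ± 0.366 CPM in siNSUN2 cells, a log2 fold change of −3.24 (SE 0.043, adjusted p = 1.64e-09), and both siNSUN2 libraries lay below both controls. HDGF (ENSG00000143321), a growth factor that the study is known for as an m5C-bearing mRNA, fell from 578 ± 8.84 to 399 ± 6.91 CPM (n = 2 each, log2 fold change −0.53, SE 0.039, adjusted p = 3.53e-06). YBX1 (ENSG00000065978), an m5C-binding protein, fell by 0.25 on the log2 scale (SE 0.041), from 1301 ± 25.7 to 1097 ± 22.3 CPM. ALYREF (ENSG00000183684), an mRNA export factor that also binds m5C, had a log2 fold change of −0.15 (SE 0.056) and narrowly missed the threshold (adjusted p = 0.0502). It passed the threshold without siControl replicate 1, at −0.28 (adjusted p = 1.62e-04), and with trends on GC content and length taken off, at −0.42 (adjusted p = 0.00862).

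Of the 16 measured m5C RNA methylation factors, 4 rose, 7 fell and 5 did not pass the test, and 4 rose and 9 fell when adjusted over the list alone. The list and its falls include NSUN2 itself, the gene targeted. TET3, an oxidase of methylated cytosine, rose the most of the called members (log2 fold change 1.25, from 32.3 ± 1.55 to 76.7 ± 0.432 CPM), and TET2 rose by 0.30. Among the relatives of NSUN2, NSUN5 rose by 0.75, whereas NSUN4, NSUN3, NSUN6 and NOP2 fell by 0.82, 0.41, 0.53 and 0.31 on the log2 scale. YBX3 rose by 0.14, and by 0.07 without siControl replicate 1. It was not called without a low-count filter (adjusted p = 0.0844). Nor was it with genes left out whose 3′ UTR holds the 6-base word ACCCTA (word-bearing genes, adjusted p = 0.148). Leaving out siControl replicate 1 or the word-bearing genes moved log2 fold changes of all shared genes by a median of −0.067 and −0.068. FMR1, 1 of 3 word-bearing members, with the longer form ACCCTAA, had a log2 fold change of −0.24 that went to 0.017 when trends on GC content and length were taken off, and NSUN3 (−0.15) and NSUN6 (−0.29) were no longer called with that correction. It also moved NSUN5 to 0.41, NOP2 to −0.56 and YBX3 to 0.34. The list as a whole did not pass (camera adjusted p = 0.214). Its median was −0.20, −0.31 without siControl replicate 1 and −0.065 with the correction.

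**Figure D1:**
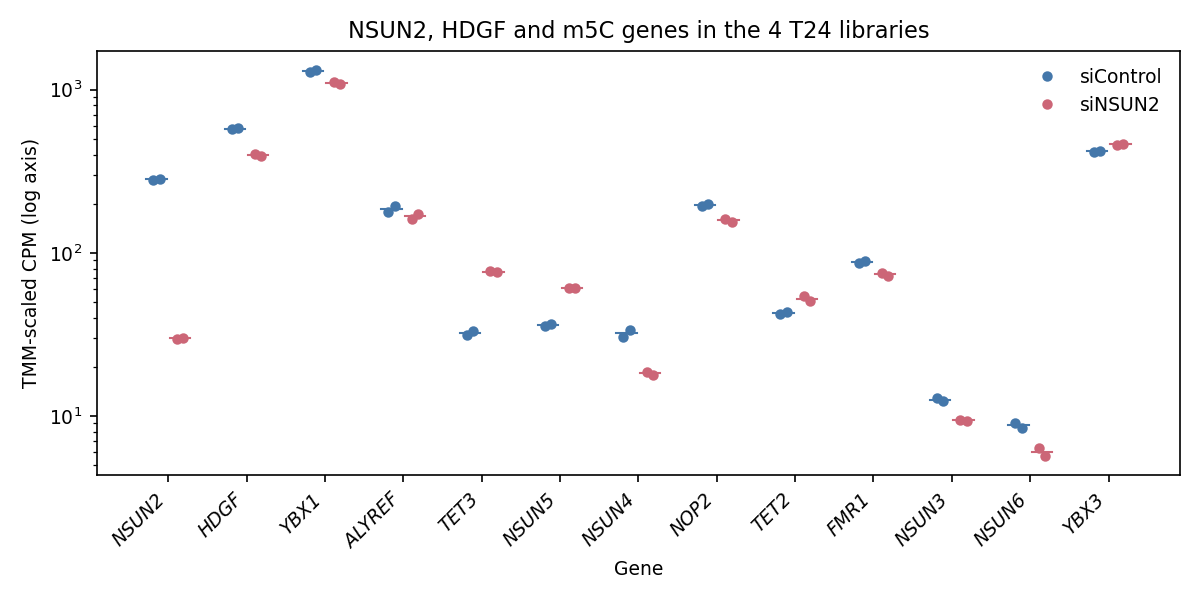
TMM-scaled CPM on a log axis for NSUN2, HDGF and the m5C genes, with 1 point per library (blue, siControl; red, siNSUN2) and a bar at the mean of the 2 libraries. NSUN2 lay at 283 CPM in siControl and 29.9 CPM in siNSUN2 cells, and the libraries of the 2 groups did not overlap for the genes drawn.

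The knockdown libraries differed from the controls over a large part of the transcriptome. Of 16889 genes tested, 4573 were higher and 4307 were lower after NSUN2 siRNA, together 52.6% of the genes. Most of these changes were small: 929 genes rose and 674 fell by 2-fold or more. Against a fold of 1.2, the test called 2913 higher and 2529 lower. Across genes, which are not independent replicates, libraries of one group correlated at 0.988 (siControl) and 0.987 (siNSUN2) in log2 CPM over genes, and libraries of different groups at 0.971 to 0.975.

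Under the rule fixed for naming genes, the largest rise was that of ANGPTL4, an inhibitor of lipoprotein lipase, from 64.4 ± 3.06 to 438 ± 3.91 CPM (log2 fold change 2.76, SE 0.047, adjusted p = 5.34e-09). It was followed by DNAJB9, a co-chaperone of the endoplasmic reticulum (ER), at 2.71, the small GTPase gene GEM at 2.53, the keratin gene KRT15 at 2.40, the semaphorin gene SEMA7A at 2.40, the interferon-stimulated gene IFI44 at 2.34 and MEGF6 at 2.29 (1.46 with GC and length taken off). After NSUN2 itself, the largest falls were those of PTER (log2 fold change −2.99, from 37.1 ± 1.70 to 4.72 ± 0.601 CPM) and of 2 pseudogenes, ZNF204P at −2.91 and ZNF252P at −2.55. The counts of these pseudogenes are uncertain, because reads can be shared with related zinc finger genes. ZNF420 fell by 2.70, the volume-regulated anion channel subunit gene LRRC8B by 2.46 and VDAC1, the main channel of the outer mitochondrial membrane, by 2.42 (from 485 ± 54.5 to 90.5 ± 6.85 CPM). The 3′ UTRs of ZNF420 and VDAC1 contain the 6-base word ACCCTA, in VDAC1 as AACCCTAA.

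Both GC content and that word went with the fold changes. Over 9591 genes with average log2 CPM above 3, the median log2 fold change was −0.22 in the 1919 genes with the lowest GC content (median GC 38.1%), where 313 genes rose and 1122 fell. It was 0.51 in the 1918 with the highest GC content (median GC 60.8%), where 1481 rose and 122 fell. For this reason the median of each gene list tested is given also with trends on GC content and transcript length taken off each library, a correction chosen after seeing the data. The corrected log2 fold change is given for each gene taken by the naming rule that it moved by over 1.5 times. Among 10528 coding genes with a searchable 3′ UTR, the 8256 without ACCCTA had a median log2 fold change of 0.06. The 279 with AACCCTAA had a median of −0.42, and 64.9% of them fell. In all, 2272 of these 10528 genes, with average log2 CPM above 1, were word-bearing, a count of 3′ UTR matches alone. Word-bearing members of lists and families, and the genes left out as word-bearing, were counted without this limit on expression. Genes whose 3′ UTR was not searched were not counted as word-bearing. Of the 8256 genes without ACCCTA, the 519 with AACCCTA in the coding sequence had a median log2 fold change of −0.30, against 0.08 for the rest. The coding sequences of HDGF, YBX1, PTER, LPIN1 and LYAR hold this word.

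**Figure D2:**
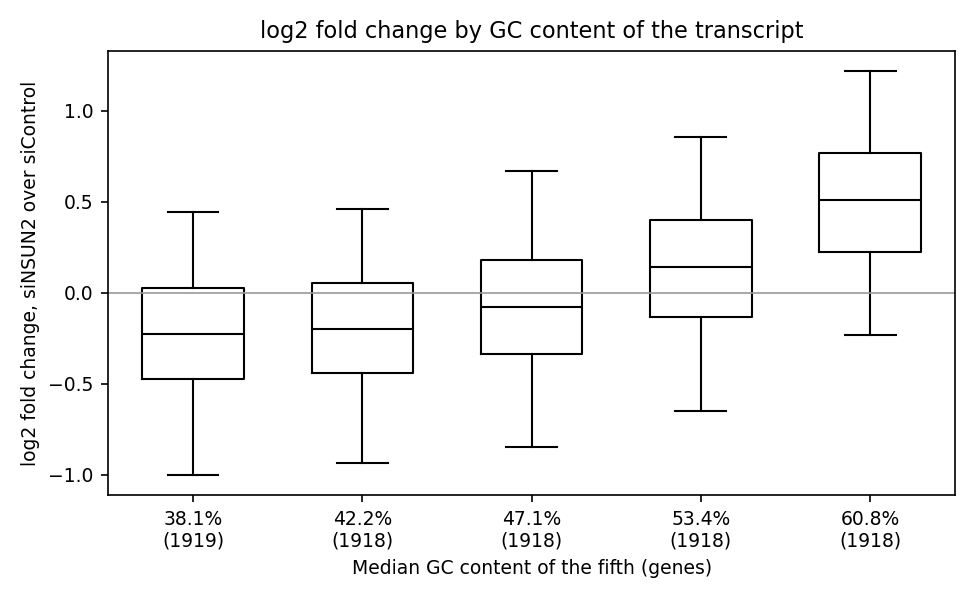
Log2 fold change, siNSUN2 over siControl, in 5 groups of genes ranked by the GC content of the longest transcript, for genes with average log2 CPM above 3. Boxes give the median and quartiles and whiskers the 5th and 95th percentiles over genes; the median runs from −0.22 in the group with the lowest GC content to 0.51 in that with the highest.

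**Figure D3:**
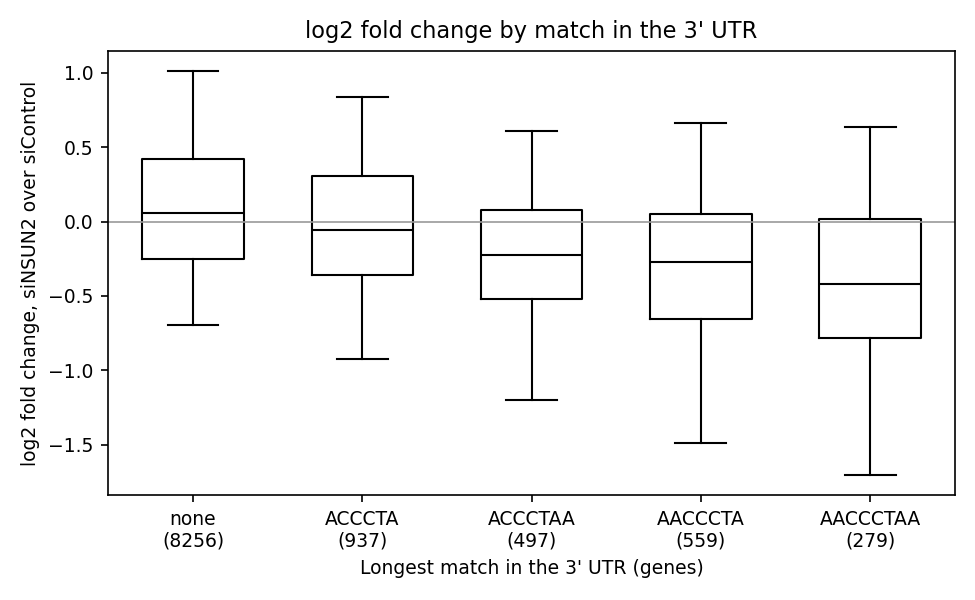
Log2 fold change, siNSUN2 over siControl, of coding genes grouped by the longest form of ACCCTA in their 3′ UTR, with the number of genes in parentheses. Boxes give the median and quartiles and whiskers the 5th and 95th percentiles over genes; the median is 0.06 without the word and −0.42 with AACCCTAA.

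Of the 34 gene lists fixed before the data were examined, 30 had enough measured members to be tested, and 18 passed with camera at its preset correlation between genes, 13 upward and 5 downward. With a correlation estimated from these 4 libraries, 0 of the 30 passed with camera after adjustment and 1 at an unadjusted p under 0.05, against 24 with fry, which tests whether a list's genes move one way on balance. Unlike camera, fry does not compare a list with other genes, and 52.6% of the genes tested were called. A pass with fry therefore does not show that a list moved apart from other genes. The 24 lists that passed with fry held 17 of the 18 and 7 others: m5C factors, DNA replication, synthetases, tRNA modification, heat shock, NSUN2 targets and glycolysis. The m5C and tRNA modification lists include NSUN2, whose fall was the aim of the siRNA, and were not tested without it. Counts adjusted over the list alone equalled those over all genes in 25 lists and are given for the other 9. With word-bearing genes left out, 25 lists passed, the 18 and 7 others, all 7 downward. Camera compares a list with all other genes, and the genes left out fell more often than the rest. These 7 passes are therefore not added support for a fall. Of the 7, the snoRNA host and mitochondrially encoded lists hold 0 members counted as word-bearing. Members whose 3′ UTR was not searched, such as MT-ND5, MT-CO2 and SNHG8, were not counted. The coding sequences of MT-ND5 and MT-CO2 hold AACCCTAA and ACCCTA. With word-bearing genes left out, the genes kept moved by a median of −0.068 on the log2 scale, and −0.067 without siControl replicate 1.

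Most ER chaperone genes, which serve protein folding in the secretory pathway, rose. Of 28 measured, 24 rose, 3 fell and 1 did not pass (median log2 fold change 0.67, and 0.63 with GC and length taken off; camera adjusted p = 1.84e-06, adjusted p = 0.623 with an estimated correlation). HERPUD1, part of the machinery that clears misfolded ER proteins, rose from 76.5 ± 0.334 to 248 ± 3.77 CPM, the chaperone gene HYOU1 from 182 ± 3.97 to 474 ± 0.578 CPM and CRELD2 from 27.0 ± 0.640 to 78.0 ± 1.00 CPM (log2 fold changes 1.70, 1.38 and 1.53). Of these 28 genes, 6 were word-bearing. Of 38 genes of ATF4 and the integrated stress response, 28 rose, 6 fell and 4 did not pass (median 0.38, and 0.21 with the correction; camera adjusted p = 3.78e-05, adjusted p = 0.623 with an estimated correlation). Their leading members were the transcription factor gene ATF3 (1.44), the mTORC1 inhibitor gene DDIT4 (1.40) and PPP1R15A (1.32), which directs dephosphorylation of eIF2α, and 6 of the 38 were word-bearing.

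Autophagy and lysosome genes also rose: 27 of 35 rose, 3 fell and 5 did not pass (median 0.70, and 0.53 with the correction; camera adjusted p = 6.93e-06, adjusted p = 0.623 with an estimated correlation). SQSTM1, an autophagy receptor, went from 574 ± 5.64 to 1906 ± 49.5 CPM (log2 fold change 1.73), with ULK1 at 1.43 (0.77 with the correction) and WIPI1 at 1.53. Of the 35 members, 6 were word-bearing. Of 23 NRF2 and oxidative stress genes, 14 rose and 4 fell, led by TRIM16L (1.67), OSGIN1 (1.40, and 0.83 with the correction) and the ferritin light chain gene FTL (1.02) (median 0.21, and 0.26 with the correction; camera adjusted p = 0.00906, adjusted p = 0.623 with an estimated correlation), and 2 were word-bearing. The median was 0.12 without siControl replicate 1 (adjusted p = 0.0201). FTL and TRIM16L have close relatives in the genome, so their counts are uncertain.

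Genes of p53 signalling and of apoptosis followed. Of 33 p53 target genes, 20 rose and 8 fell (median 0.47, and 0.23 with the correction; camera adjusted p = 0.00933, adjusted p = 0.623 with an estimated correlation), and 9 were word-bearing. GDF15, a stress-induced cytokine, rose from 51.1 ± 0.335 to 228 ± 3.70 CPM (log2 fold change 2.16), and CDKN1A, the inhibitor of cyclin-dependent kinases p21, from 110 ± 3.22 to 237 ± 0.258 CPM (1.11). The call of this list was lost with a filter at a mean of 5 CPM (adjusted p = 0.055). CDKN1A and TRAF4 (0.86, and 0.57 with the correction) rose although their 3′ UTRs contain ACCCTA. Of 30 apoptosis regulators, 18 rose and 3 fell (median 0.36, and 0.20 with the correction; camera adjusted p = 0.00457, adjusted p = 0.623 with an estimated correlation), and 8 were word-bearing. BBC3, a pro-apoptotic BH3-only gene, rose by 1.72 (0.88 with the correction), and CYCS, which encodes cytochrome c, an activator of caspases once released from mitochondria, fell by 0.69.

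Inflammatory genes rose: of 33 NF-kB and inflammatory genes, 29 rose, 2 fell and 2 did not pass, with 30 and 2 adjusted over the list alone (median 0.92, and 0.75 with the correction; camera adjusted p = 5.26e-08, adjusted p = 0.623 with an estimated correlation). CSF1, the macrophage growth factor gene, rose from 10.7 ± 0.198 to 39.3 ± 1.53 CPM (log2 fold change 1.88), and the chemokine gene CXCL2 from 21.1 ± 0.884 to 53.4 ± 0.453 CPM (1.33). The smallest p of the list belonged to a fall, that of SOD2, the mitochondrial superoxide dismutase gene (−1.47), 1 of its 3 word-bearing members, with AACCCTA. Of 47 interferon-stimulated genes, 30 rose, 6 fell and 11 did not pass, with 31 and 6 adjusted over the list alone (median 0.64, and 0.60 with the correction; camera adjusted p = 2.09e-05, adjusted p = 0.623 with an estimated correlation). IRF7 rose from 11.2 ± 0.00429 to 34.8 ± 0.461 CPM (1.63, and 0.92 with the correction) and IFIT2 from 5.16 ± 0.239 to 20.8 ± 0.709 CPM (2.01). OAS3, 1 of the 10 word-bearing members, fell from 181 ± 0.425 to 93.3 ± 3.61 CPM (−0.96).

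Genes of cell division went the other way. Of 54 genes of G2 and mitosis, 43 fell, 2 rose and 9 did not pass (median −0.45, and −0.33 with the correction; camera adjusted p = 1.67e-09, adjusted p = 0.623 with an estimated correlation), and 7 were word-bearing. The kinetochore motor gene CENPE fell from 138 ± 1.15 to 29.2 ± 0.953 CPM (log2 fold change −2.24), KIF20B by 1.24, and GTSE1, with AACCCTA in its 3′ UTR, by 1.34. DNA replication and S phase genes were divided: 23 of 49 fell and 10 rose, and the list did not pass (median −0.14, and −0.16 with the correction; camera adjusted p = 0.0767). It passed without siControl replicate 1 (adjusted p = 0.0318, median −0.20) and with the word-bearing genes left out (adjusted p = 0.0114, median −0.21), and its median was −0.07 both without siControl replicate 2 and without siNSUN2 replicate 1. MCM4, a subunit of the replicative helicase and word-bearing, fell by 0.91, and the phosphatase gene CDC25A rose by 0.85. Replication-dependent histone genes, whose mRNAs mostly lack poly(A) tails, were higher in poly(A) RNA: 10 of 16 rose and 6 did not pass (median 0.84, and 0.82 with the correction; camera adjusted p = 4.9e-04, adjusted p = 0.623 with an estimated correlation), among them H1-2 (1.28), H2AC6 (1.29) and H2BC12 (0.89, and 0.51 with the correction), with 2 members word-bearing. Histone genes of this kind are similar in sequence, so their counts are uncertain.

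**Figure D4:**
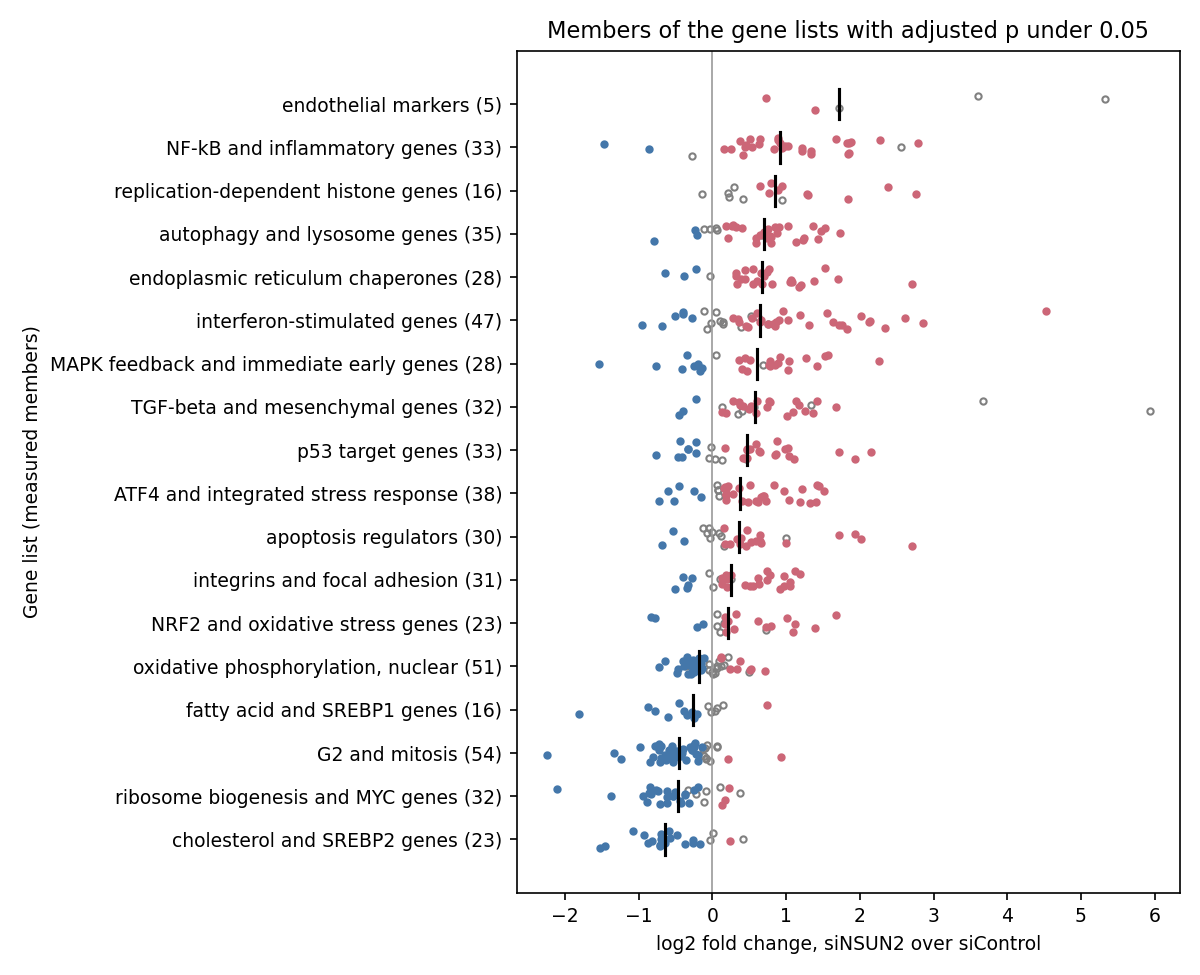
Log2 fold change, siNSUN2 over siControl, of every measured member (1 point each) of the 18 gene lists that passed camera at its preset correlation. Red points rose, blue points fell and open points did not pass the test, and black bars mark medians, from −0.64 for cholesterol genes to 0.92 for NF-kB genes and 1.71 for the 5 endothelial markers.

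Lipid synthesis genes fell. Of 23 cholesterol genes, 19 fell, 1 rose and 3 did not pass (median −0.64, and −0.55 with the correction; camera adjusted p = 1.84e-06, adjusted p = 0.623 with an estimated correlation). IDI1, an isomerase gene of the mevalonate pathway, fell from 189 ± 2.57 to 68.9 ± 2.53 CPM (log2 fold change −1.46) and ACAT2 from 334 ± 2.06 to 176 ± 6.21 CPM (−0.92). IDI1 was among the 5 word-bearing members and ACAT2 was not. Of 16 fatty acid genes, 10 fell and 1 rose (median −0.26, and −0.35 with the correction; camera adjusted p = 0.011, adjusted p = 0.623 with an estimated correlation), led by the desaturase gene SCD (−1.81, word-bearing, as were 3 of the list), LPIN1 (−0.87) and the elongase gene ELOVL6 (−0.78).

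Genes of ribosome production fell as well. Of 32 ribosome biogenesis and MYC genes, 23 fell, 3 rose and 6 did not pass, with 24 and 3 adjusted over the list alone (median −0.47, and −0.53 with the correction; camera adjusted p = 1.95e-06, adjusted p = 0.623 with an estimated correlation). DKC1, the pseudouridine synthase gene of H/ACA particles, fell from 256 ± 0.894 to 59.1 ± 0.482 CPM (log2 fold change −2.11), LYAR by 1.38 and NOLC1 by 0.86. The 3′ UTRs of DKC1 (AACCCTAA) and NOLC1 (AACCCTA) held the word, as did those of 5 members in all. For the cytosolic ribosomal proteins, 33 of 79 fell and 17 rose, 35 and 17 adjusted over the list alone, and the list narrowly missed the threshold (median −0.14, and −0.095 with the correction; camera adjusted p = 0.0531). RPS20 fell by 0.81 and RPS28 rose by 0.80 (0.42 with the correction), and many genes of this list share reads with processed pseudogenes. The list passed without siControl replicate 1 (adjusted p = 0.00528, median −0.24), without siNSUN2 replicate 1 (adjusted p = 0.0326, median −0.15) and with the word-bearing genes left out (adjusted p = 0.00702, median −0.21), and its median was −0.07 without siControl replicate 2. It also passed with GC and length taken off (adjusted p = 0.046), with RLE factors (adjusted p = 0.0437) and with upper-quartile factors (adjusted p = 0.0443). Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs, gave 12 falls and 5 rises among 23 (median −0.35, and −0.28 with the correction; camera adjusted p = 0.0507), and passed without siControl replicate 1 (adjusted p = 0.0187) and without siNSUN2 replicate 1 (adjusted p = 0.0214). This list also passed with GC and length taken off (adjusted p = 0.0091), with the word-bearing genes left out (adjusted p = 0.00228), with RLE factors (adjusted p = 0.0423), with upper-quartile factors (adjusted p = 0.0444) and without a low-count filter (adjusted p = 0.0211). FARSB fell by 0.81 and NARS1 by 0.60. Among 35 tRNA modification enzymes, 17 fell and 8 rose, 17 and 9 adjusted over the list alone (median −0.08, and −0.25 with the correction; camera adjusted p = 0.128), and the list passed with GC and length taken off (adjusted p = 7.54e-04) and with the word-bearing genes left out (adjusted p = 0.0358, median −0.15). Its median was −0.17 without siControl replicate 1 and −0.14 without siNSUN2 replicate 1. Its members included a fall of NSUN2 itself and a rise of 1.07 (0.71 with the correction) in RNH1, the ribonuclease inhibitor gene. Of 17 snoRNA host genes, 6 fell and 3 rose (median −0.11, and −0.13 with the correction; camera adjusted p = 0.0767), with TAF1D at −0.70 (−0.44 with the correction) and SNHG8 at −0.47. This list passed without siControl replicate 1 (adjusted p = 0.0244, median −0.25), without siNSUN2 replicate 1 (adjusted p = 0.0344, median −0.20) and with the word-bearing genes left out (adjusted p = 0.0294, median −0.18).

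Among genes of mitochondrial respiration, more fell than rose. Of 51 nuclear genes of oxidative phosphorylation, 29 fell and 8 rose, 29 and 9 adjusted over the list alone (median −0.18, and −0.13 with the correction; camera adjusted p = 0.0229, adjusted p = 0.697 with an estimated correlation). This call was lost without siNSUN2 replicate 2, where the median was −0.12 (adjusted p = 0.154). It was also lost with fry, another test of the same values (adjusted p = 0.175). ATP5PB fell by 0.64, NDUFA5 by 0.73 (−0.47 with the correction) and UQCRC2 by 0.48, and NDUFA5 was 1 of 7 word-bearing members. Of 13 mitochondrially encoded mRNAs, 7 fell and 1 rose, and the list did not pass (median −0.30, camera adjusted p = 0.0531). With GC and length taken off its median was −0.13 (adjusted p = 0.319). MT-ND5 went from 1207 ± 16.5 to 875 ± 25.7 CPM and MT-CO2 from 2736 ± 3.96 to 1978 ± 139 CPM. The list passed without siControl replicate 1 (adjusted p = 0.0209, median −0.44), without siNSUN2 replicate 1 (adjusted p = 0.0123, median −0.47), without a low-count filter (adjusted p = 0.0316) and with the word-bearing genes left out (adjusted p = 0.0241). Glycolysis and hypoxia genes split into 12 rises and 8 falls among 32 (camera adjusted p = 0.599). ANGPTL4 rose, as did the lactate transporter gene SLC16A3 (1.35, and 0.77 with the correction). The list median was 0.02, and −0.17 with the correction. It was −0.04 without siControl replicate 1, −0.004 without siControl replicate 2, −0.027 without siNSUN2 replicate 1 and 0.071 without siNSUN2 replicate 2.

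Adhesion and mesenchymal genes rose. Of 32 TGF-beta and mesenchymal genes, 22 rose, 3 fell and 7 did not pass, with 26 and 3 adjusted over the list alone (median 0.58, and 0.46 with the correction; camera adjusted p = 1.26e-05, adjusted p = 0.623 with an estimated correlation), and 10 were word-bearing. VIM, the intermediate filament gene of mesenchymal cells, rose from 1035 ± 21.7 to 1762 ± 8.98 CPM (log2 fold change 0.77), with COL6A1 at 1.68 (1.07 with the correction) and ITGA5 at 0.74. The list includes 3 genes of matrix proteins and proteases, MMP2, SPARC and MMP14, that did not pass and were highest in siNSUN2 replicate 2, where CDH5, VWF and HBB, markers of other cell types, were also highest. MMP2 stood at 0.577 CPM in siNSUN2 replicate 1 and 3.21 CPM in siNSUN2 replicate 2, against 0 and 0.0376 CPM in the controls (adjusted p = 0.0584). SPARC stood at 0.0941 ± 0.0332 CPM in siControl and 1.37 ± 1.41 CPM in siNSUN2 cells (adjusted p = 0.0778), and MMP14 at 0.360 ± 0.0430 and 0.957 ± 0.630 CPM (adjusted p = 0.0595). Of 31 integrin and focal adhesion genes, 21 rose and 5 fell, 22 and 5 adjusted over the list alone (median 0.26; camera adjusted p = 0.00142, adjusted p = 0.623 with an estimated correlation), and 8 were word-bearing. This call was lost when GC and length were taken off (median 0.14, adjusted p = 0.0592), and without siControl replicate 1 the median was 0.17 (adjusted p = 0.00812). BCAR1 rose by 1.06 although its 3′ UTR holds AACCCTA, ITGA2 by 0.97 and LAMA5 by 0.78, and with the correction BCAR1 went to 0.46 and LAMA5 to −0.024. Of 28 MAPK feedback and immediate early genes, 18 rose and 8 fell (median 0.60, and 0.46 with the correction; camera adjusted p = 0.0141, adjusted p = 0.623 with an estimated correlation). JUNB rose by 1.56 (0.95 with the correction) and HBEGF by 1.03, whereas ETV5, 1 of 8 word-bearing members, fell by 1.54, and the call of this list was lost with a filter at a mean of 5 CPM (adjusted p = 0.0791). YAP and TEAD target genes moved both ways, with 9 rises and 6 falls among 21 (camera adjusted p = 0.884). Their median was −0.03, and −0.07 with the correction. It was −0.095 without siControl replicate 1, −0.059 without siNSUN2 replicate 1 and 0.004 without siNSUN2 replicate 2. GADD45B rose by 0.89 (0.51 with the correction) and the receptor tyrosine kinase gene AXL, which is word-bearing, fell by 1.52.

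Of 22 cytosolic heat shock genes, 13 fell and 5 rose. Their median (−0.26, and −0.29 with the correction) and their mean (0.04) differed in sign, and the list did not pass (camera adjusted p = 0.0979), although it did without siNSUN2 replicate 1 (adjusted p = 0.0431), with the word-bearing genes left out (adjusted p = 0.0295), with a filter at a mean of 5 CPM (adjusted p = 0.0348) and with GC and length taken off (adjusted p = 0.0159). HSPH1 fell by 0.96 and HSPB1 rose by 1.13 (0.56 with the correction). Of 10 mRNAs described as NSUN2 targets, 6 rose and 2 fell (median 0.27, and −0.03 with the correction; camera adjusted p = 0.179). HDGF fell and CDKN1A rose, and since HDGF is known from this study, its fall is not independent evidence for the list.

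Among markers of urothelial cell types, 3 of 14 luminal markers rose and 3 fell (camera adjusted p = 0.839). Their median was −0.10, and −0.32 with the correction. It was −0.22 without siControl replicate 1, −0.044 without siControl replicate 2 and −0.054 without siNSUN2 replicate 2. PPARG rose by 0.72, and ERBB2 rose by 0.39 and was not called with GC and length taken off (0.033). Only 3 basal markers were measured, of which EGFR, word-bearing, fell from 514 ± 2.71 to 327 ± 13.4 CPM and CD44 fell by 0.15. The third, KRT17, was at 0 counts in both controls and at 0.215 ± 0.0266 CPM in siNSUN2 cells, at least 17.5-fold higher when 3 counts over the control group are taken as the floor, which covers counting error only.

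Few markers of other cell types were measured. Of 5 endothelial markers, 2 rose, ESAM at 1.39 and EGFL7 at 0.73 (median 1.71, and 1.5 with the correction; camera adjusted p = 0.0484, adjusted p = 0.667 with an estimated correlation). Without siControl replicate 1 the median was 3.33 (adjusted p = 0.0209). The call was lost without siControl replicate 2 (adjusted p = 0.0607), with upper-quartile factors (adjusted p = 0.0516), with total library sizes (adjusted p = 0.0576) and with GC and length taken off (adjusted p = 0.173), where EGFL7 went to −0.049. CDH5 stood at 0.376 ± 0.133 CPM in siControl and 1.22 ± 0.914 CPM in siNSUN2 cells, which did not pass (adjusted p = 0.078) but did without siNSUN2 replicate 1 (adjusted p = 0.00873), with DESeq2 (adjusted p = 0.0384) and without a low-count filter (adjusted p = 1.41e-04). VWF was at 1.80 CPM in siNSUN2 replicate 1 and 8.73 CPM in siNSUN2 replicate 2, against 0.165 and 0.113 CPM in the controls (adjusted p = 0.0814). Of 3 fibroblast and stromal markers, FBLN1 rose from 233 ± 1.26 to 361 ± 3.28 CPM (log2 fold change 0.64, and 0.34 with the correction) and COL1A1 from 1.24 ± 0.558 to 3.11 ± 0.270 CPM, a call that was lost without siNSUN2 replicate 1 (adjusted p = 0.0851), as it was without siNSUN2 replicate 2 (adjusted p = 0.106) and with GC and length taken off (log2 fold change 0.78 against 1.28, adjusted p = 0.0865). The single leukocyte marker measured (ITGAM, adjusted p = 0.0903) and the 2 erythroid markers (HBB, adjusted p = 0.506, and HBA2, adjusted p = 0.77) did not pass. HBB was at 2.66 CPM in siNSUN2 replicate 2, at 0.188 CPM in siControl replicate 2 and at 0 in the other libraries.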

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

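Of the settings below, thinning, leaving out word-bearing genes and the GC and length correction were chosen after seeing the data. The NSUN2 log2 fold change kept its direction and stayed past the threshold under every setting run, between −3.09 (GC and length correction) and −3.32 (without siControl replicate 1). The numbers of genes higher and lower stayed within 1.5 times of 4573 and 4307, except with a fold of at least 2 (929 and 674) and a test against a fold of 1.2 (2913 and 2529), which by construction ask for larger changes. Leaving out single libraries gave 3720 to 4231 genes higher and 3750 to 4695 lower, a lone library being assumed to vary like the other group. DESeq2 called 4004 and 4125, and 89.7% of the called genes were called by it in the same direction. With GC and length taken off, 70.4% kept their call and direction and 327 of the called genes were called the opposite way.

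Of 30 gene lists tested, 18 passed, against 0 with an estimated correlation (2 samples a group leave 2 residual degrees of freedom), 24 with fry (17 of the 18 and 7 others) and 15 to 25 of 28 to 34 lists in other settings, with no called list reversed. The number with fry answers another question, since fry does not compare a list with other genes. Without single libraries the number was 17 to 23. Among named genes, only the GC and length correction gave reversed signs, for FMR1 (0.017), LAMA5 (−0.024) and EGFL7 (−0.049), none of them past the threshold there, and the cause was not tested. ALYREF passed in 6 settings, including DESeq2, at −0.18. KRT17 and genes under 1 CPM rest on few counts in the shallower libraries.

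The replicate numbers are shared between the groups but nothing says that they mark a shared day, and with 2 pairs the data cannot show it. Deviations of same-numbered libraries correlated at 0.156 over all tested genes and 0.0878 above a log2 CPM of 3. Above that level, differences between replicates correlated between the groups at −0.38 (Spearman 0.178) over coding genes and 0.82 over pseudogenes. The sign thus varied with the genes taken and, over the same coding genes, with the measure of correlation, and no crossed pairing is reported. With the replicate block, 5027 genes were higher and 4788 lower, the endothelial list did not pass (adjusted p = 0.0547), and CDH5 passed (adjusted p = 5.45e-04), as did ALYREF (adjusted p = 0.00104) and the ribosomal protein list (adjusted p = 0.0313).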

Other observations

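Of the tests in this part, those on gene families, words in coding sequences with and without zinc finger genes, telomere-like repeats, microRNA words and GC differences between libraries, the comparison of single libraries, the thinning of libraries and the correction for GC and length were chosen after the results were seen. Coding genes grouped by the letters that open their symbols formed 87 families of at least 15 measured members, and 6 passed camera at its preset correlation, and 0 with an estimated one (adjusted p = 0.957 for each of the 6, and 0 of the 87 at an unadjusted p under 0.05). Zinc finger genes (ZNF) fell in number: 231 of 422 fell and 59 rose (median log2 fold change −0.31, and −0.27 with GC and length taken off; camera adjusted p = 1.57e-06), with ZNF664 at −1.93 and, against the direction of the family, ZNF367 at 1.38. Of these 422 genes, 143 were word-bearing. Among the searched ZNF genes that were not, 246 had average log2 CPM above 1. Of these, the 99 with AACCCTA in the coding sequence had a median of −0.65. There AACCCTA is part of a common form of the linker between zinc fingers. The 147 with neither match had a median of 0.04, with 48 rises and 42 falls. Of 28 MRPS genes, for the small subunit of the mitochondrial ribosome, 19 fell and 1 rose (median −0.29, and −0.22 with the correction; camera adjusted p = 0.00495), with MRPS27 at −0.76. Of 47 MRPL genes, for its large subunit, 23 fell, 6 rose and 18 did not pass (median −0.16, and −0.26 with the correction; camera adjusted p = 0.0231), with MRPL50 at −0.95. Of 53 EIF genes, most of which encode translation initiation factors, 27 fell and 4 rose (median −0.16, and −0.17 with the correction; camera adjusted p = 0.0109), led by EIF3M at −1.78.

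Genes of the SEC family, most of which serve protein translocation into the ER and vesicle transport, rose: 16 of 23 rose and 1 fell (median 0.29 with and without the correction; camera adjusted p = 0.0113). SEC61A1, a subunit of the translocation channel, rose by 0.80 although its 3′ UTR holds ACCCTA, and SEC24D, of the vesicle coat, rose by 1.06. Of 39 IL genes, most of which encode interleukins and their receptors, 18 rose and 4 fell (median 0.45, and 0.46 with the correction; camera adjusted p = 0.0238), among them IL6 from 8.74 to 27.8 CPM and IL6R from 5.07 to 19.9 CPM.

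The genes that fell shared a short word in their 3′ UTRs: among 16166 words of 7 bases, AACCCTA had the lowest z score, −18.1 over 838 genes, 3.48 times that of the next unrelated word (TCTCTAC, −5.21), while 100 shuffles went no lower than −4.85, and falls were larger with longer matches, from a median of −0.06 with ACCCTA alone to −0.42 with AACCCTAA, or −0.07 to −0.28 with GC and length taken off. Among the 8256 genes without ACCCTA there, AACCCTA also had the lowest z score of words in coding sequences, −15.9 over 519 genes. Their median log2 fold change was −0.30, against 0.08 without the word. Zinc finger genes are argued against as the whole source of this. With 304 of them left out, the z score of AACCCTA was −11.3 over 399 genes (median −0.24, against 0.08 without it). The lowest z score of 100 shuffles was then −4.65. AACCCTA then ranked 2, after the shifted word ACCCTAA, with 2.16 times the score of the lowest unrelated word (GCGGCGC). Telomere-like repeats are argued against, since the weakest rotation of the repeat unit reached only 0.159 of the strongest z score. AACCCTA occurs 1 time in the NSUN2 mRNA, in the coding sequence (16.2% of all words scored in 3′ UTRs occur in its coding sequence or 3′ UTR). A candidate explanation is therefore that an siRNA against NSUN2 acted on other mRNAs through its seed, as a microRNA would. Of 346 searched genes that fell 2-fold or more, 210 (60.7%) were word-bearing, against 2062 of 10182 others (20.3%). Of all 3696 that fell, 1141 (30.9%) were, against 21.6% of all genes searched. These shares describe and do not test, since the word was found from the same fold changes. Of genes without ACCCTA in the 3′ UTR 30.9% fell too, so a match does not assign a fall to the seed. Another 325 falls held AACCCTA in the coding sequence, which leaves 2230 (60.3%) without either. Other forms in coding sequences were not counted, and HSPH1 and RPS20, among the 2230, hold ACCCTAA there. The sequence and number of the siRNAs against NSUN2 are not given in the sources used here, so the word could not be compared with a seed. Loss of NSUN2 stays open for all of these falls, with or without a match, and for the gene groups. An indirect effect of either kind stays open for them as well. A seed match also stays open for word-bearing falls and for genes such as HDGF, YBX1, PTER, LPIN1 and LYAR, whose coding sequences hold AACCCTA. The same is true of falls such as HSPH1 and RPS20, whose coding sequences hold ACCCTAA.

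The rise of log2 fold change with GC content (Pearson 0.486 across 11485 genes, which are not independent) separated the groups. GC bias that varies from library to library is argued against, since the largest slope within a group was 0.0361 of the smallest slope between groups. A GC bias of a preparation or sequencing batch that follows the groups cannot be told apart from a biological effect of the knockdown: among 135 lincRNA genes, which such a bias should reach as it reaches mRNAs, the slope was 0.171 per 10 percentage points of GC (95% bootstrap interval 0.052 to 0.288), whereas such a bias was set to need at least 2 of 3 of the 0.324 among coding genes, and an upper bound under 1 of 3 of it to be excluded, and neither was met. GC content and length do not account for the whole number of genes called, since 70.4% of calls kept their direction with the correction, and nor does depth, since 8394 genes were called against 8880 when all libraries were thinned to the shallowest. A biological source of the GC trend was not tested.

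The genes that rose shared no single word that stood apart. The highest z score, 5.46 for CGTTTTA, lay above the highest of 100 shuffles (4.84) but was 1.02 times that of the next unrelated word (TTTGCAC, 5.37). A gap of 1.5 times had been set beforehand. The small gap argues against a single seed of control siRNA as the main source of the rises. It leaves open a smaller effect, and an effect spread over several seeds, which the test could not detect. Competition of the siRNA with microRNAs might also raise their targets: leaving out 5 families seen among the highest words, words of 14 microRNA families common in epithelial cells had a mean z score 1.25 above that of 11 tissue-restricted families (permutation p = 0.0567), which leaves this open. An effect of NSUN2 loss on the genes that rose was not tested apart from the siRNA.

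Of 9274 coding genes with average log2 CPM above 3, 16 were at least 2-fold higher in siControl replicate 2 than 1 and in siNSUN2 replicate 1 than 2, the deeper library of each pair, and 0 the opposite way in both. MIF, for example, stood at 3.95 and 34.3 CPM in the control libraries and at 87.5 and 6.02 CPM in the siNSUN2 libraries, and MT-ATP8 at 31.5, 160 and 318, 14.6 CPM. Some of the 16 belong to tested lists: MT-ATP8 to the mitochondrially encoded mRNAs, RPL26, RPL17 and RPS15A to the ribosomal proteins, and ATP5PO to oxidative phosphorylation. MRPL12 and EIF3L belong to the MRPL and EIF families that passed. Between the groups, 0 of the 16 were called.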
